A study of Homo sapiens with 519 samples.

How the data were processed

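RNA was measured in 519 libraries of the SK-N-BE(2) cell line from 4 experiments, each deposited as a table of counts per gene symbol. The deposited values are counts: whole numbers whose totals differ between libraries. The authors named the aligner STAR and the build GRCh38 without versions, and did not state the read counter, the annotation, any filter or the handling of reads that map to several places. No step that collapses molecular identifiers was stated, so intervals and errors take each read as counted. The tables hold 44267 genes and 92 spike-in sequences in the first experiment, 25559 genes in the second, 57728 in the third and 25392 in the TruSeq experiment. The second table lacks the mitochondrially encoded genes, and 374 of the 391 list members are in it; the other tables hold all 391. The labels give doses in the first experiment and the third mostly without a unit and in the second in mM.

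Groups were taken from the labels. In the first experiment each plate has 4 DMSO wells and 2 wells without DMSO by the labels, whereas the stated protocol gives 6 DMSO wells; the labels were followed. Replicate numbers did not pair libraries of different treatments in the TruSeq experiment, the second and the third, where the median correlation of residuals between equal numbers was −0.0041, −0.001 (6 h), 0.0037 (24 h) and 0.0066. In the first experiment it was 0.602, and all 180 compound libraries were closest to those of their own plate, so the plate was a block there. No 2 columns of a table were identical. Mock-treated libraries carry conflicting time labels and were kept as 1 group.

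Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 13438 genes in the first experiment, 11460 (6 h) and 11539 (24 h) in the second, 15596 in the third and 15329 in the TruSeq experiment. Libraries were scaled by trimmed means of M values, and all groups of an experiment (of a time point in the second) were fitted together by glmQLFit with bias-adjusted deviances and tested by glmQLFTest, two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The SE of a log2 change is its size divided by the square root of the F statistic, and 95% intervals use the quasi-likelihood degrees of freedom. CPM values use the scaled library sizes. Correlations across genes were computed on fitted log2 changes; where 2 contrasts shared controls, 10 simulated data sets without a treatment effect gave the value that sharing alone produces, and in the third experiment the DMSO wells were split into 5 and 4 so that the contrasts shared none.

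The 21 gene lists were fixed before the data were examined: MYC targets, ribosome biogenesis, adrenergic identity, the mesenchymal state, NRF2, ATF4, the unfolded protein response, heat shock, cholesterol biosynthesis, hypoxia and glycolysis, G2 and mitosis, S phase, p53 targets, immediate early genes, the aryl hydrocarbon receptor, metallothioneins and zinc, YAP and TEAD targets, FOXO and PI3K feedback, lysosome and autophagy, mitochondrially encoded genes and markers of other cell types. In the TruSeq experiment they were tested by camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 21 lists. Named genes followed a rule fixed in advance for 8 main comparisons: the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap and whose mean reached 5 CPM (TruSeq) or 30 CPM (plates) in a group, the 3 members with the smallest p of each list that passed its set test or had at least 3 members past the threshold, and MYCN, TEAD4, CSNK2A1, CSNK2A2 and CSNK2B. Superlatives in the report refer to genes that meet those conditions. Symbols of uncharacterised loci were left out. Other comparisons name genes from the same selection, picked after their values were seen.

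The procedure was tested on simulated data in which 200 genes were changed 1.5-fold, 2-fold or 4-fold. Over 3 sets for each, 4.75% of the calls were false in the TruSeq experiment (22 of 463), 15.3% in the third experiment (27 of 177) and 10% in the second (12 of 120), and 92.3%, 66.3% and 46.9% of the 4-fold changes were found. For the plates this false share is above the nominal 5%; with the older quasi-likelihood method it was 5.93% in the third experiment (8 of 135) and 3.7% in the second (3 of 81), so small counts from the plates should be read beside those of the older method. In the first experiment, with 2 wells against 8 and 1 set, 8 calls held 1 false one, and 11.3% of the 4-fold changes were found. The spread of that set came from a fit without the plate as a block, and each simulated plate also kept its own means. Differences between plates thus entered both the spread and the means, so the share found there may be too low. No call went in the wrong direction in any of these sets. At 2-fold, 78% of the changes were found in the TruSeq experiment, 10% in the third experiment and 7.18% in the second, so the plates show mainly large changes.

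Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, no filter on low counts, the DESeq2 Wald test, a block for the replicate number (none in the first experiment), leaving out each replicate number in turn, a fit of only the compared groups (TruSeq), pooling both kinds of control wells (first experiment) and the estimated correlation in camera. Leaving out a replicate number removes its library from every group. The plan named edgeR's quasi-likelihood test without saying which of its 2 methods. The bias-adjusted method was chosen because it fits faster, after counts from the older method had been seen, and the older method was added as an alternative outside the first experiment. The regrouping used for the effect of time was also chosen after a first version had been seen. Libraries were also regrouped at random, or in every possible way where few exist, to count how often other groupings give as many genes. Coordinates are from the GRCh38.p14 annotation.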

Results

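Gene expression was measured in 519 RNA-seq libraries of SK-N-BE(2), an established human neuroblastoma cell line in which the MYCN gene is amplified. The libraries came from 4 experiments. The first exposed cells for 24 h to 90 compounds picked for selectivity towards MYCN-amplified lines, each on 2 plates, and holds 192 libraries, of which 8 are DMSO wells and 4 are wells without DMSO by their labels, although the stated protocol describes only DMSO wells as controls. The second tested 15 compounds at 2 concentrations for 6 h and 24 h in 3 replicates, with 6 control wells per time, and also holds 192 libraries. The third tested 29 treatments in 3 replicates for 24 h beside 9 DMSO wells, in 96 libraries. Most of these treatments were relatives of isopomiferin, a prenylated isoflavone, or kinase inhibitors. These experiments used PLATE-seq, a 3′-end method that barcodes the wells of a plate and sequences them as a pool. The fourth used TruSeq libraries of cells exposed for 3 h or 6 h to isopomiferin or pomiferin at 3 or 10 µM, to a null analog at 10 µM, or to DMSO, and of mock-treated cells, with 3 libraries per group and 39 in total. Total counts per library ran from 38670 to 3958909 in the first experiment (median 1790617), from 608491 to 1901416 in the second (median 1332697), from 706208 to 5263249 in the third (median 3060676.5) and from 17209306 to 33280770 in the TruSeq experiment (median 24777169). The labels do not say whether replicates were separate cultures, so every error and p-value below describes the spread between these libraries.

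The TruSeq experiment asked which kinases the isoflavones act on, from the early response to isopomiferin, pomiferin and the null analog. After 6 h at 10 µM, isopomiferin raised the genes of the integrated stress response, the program run by the transcription factor ATF4, and of the unfolded protein response of the endoplasmic reticulum. GDF15, a stress-induced cytokine, showed the largest rise, by 5.53 ± 0.20 on the log2 scale (SE, n = 3 per group), from 0.536 to 24.5 CPM (counts scaled to a common library size). CHAC1, a glutathione-degrading enzyme and ATF4 target, rose by 4.87 ± 0.26, the activin subunit INHBE by 5.20 ± 0.30, the transcription factor DDIT3 by 3.83 ± 0.13 and the pseudokinase TRIB3 by 3.93 ± 0.12. HSPA5, the main chaperone of the endoplasmic reticulum, rose by 3.08 ± 0.07, from 513 to 4328 CPM, and the disulfide isomerase PDIA4 by 1.83 ± 0.04. All 24 measured members of the ATF4 list and all 17 of the unfolded protein response list rose. So did 16 of 19 NRF2 oxidative stress genes (17 adjusted over the list alone), among them the heme oxygenase HMOX1 (3.37 ± 0.11) and the cystine transporter SLC7A11 (2.73 ± 0.13). Of 22 cholesterol biosynthesis genes 18 rose (19 adjusted over the list alone), with INSIG1, a sterol-responsive regulator, at 0.95 ± 0.05 and the demethylase CYP51A1 at 1.00 ± 0.06.

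Neuroblastoma identity and cell-cycle genes fell in the same libraries. Of 20 adrenergic identity genes 11 fell and 3 rose (12 and 3 adjusted over the list alone). Among their transcription factors HAND1 fell by 1.03 ± 0.05 and GATA2 by 0.69 ± 0.05. Of 24 G2 and mitosis genes 20 fell (22 adjusted over the list alone), such as the mitotic kinase AURKA (−0.52 ± 0.05) and the topoisomerase TOP2A (−0.44 ± 0.05). Of 22 S phase genes 11 fell and 1 rose, and of 22 ribosome biogenesis genes 10 fell and 2 rose. The largest falls were those of the homeobox gene DRGX (−1.88 ± 0.17), CCDC177 (−1.84 ± 0.20) and the adhesion gene MDGA1 (−1.59 ± 0.43). MYCN itself (chromosome 2, 15940550 to 15947004, GRCh38.p14), at 3778 CPM in DMSO, was at −0.08 ± 0.05 and did not pass the test (adjusted p = 0.264). Of the genes for subunits of the kinase CK2, CSNK2A2 rose by 0.16 ± 0.04 (adjusted p = 0.00668) and CSNK2B by 0.13 ± 0.05 (adjusted p = 0.0287), while CSNK2A1 was at −0.00 ± 0.06 (adjusted p = 0.978; 0.04 without replicate 1). By edgeR's quasi-likelihood test 3892 of 15329 genes passed, 2061 higher and 1831 lower, and 339 of these changed at least 2-fold (254 up, 85 down). All 3 treated libraries lay on one side of all 3 DMSO libraries for 37.6% of genes, where chance gives 10%. Without replicate 2 the count was 2472. CSNK2A2 (0.16 and 0.12) and CSNK2B (0.10 and 0.13) no longer passed without replicates 2 and 3, nor CSNK2B with low-count genes kept (0.13), nor MDGA1 without replicates 1 and 2 (−1.42 and −1.47).

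**Figure D1:**
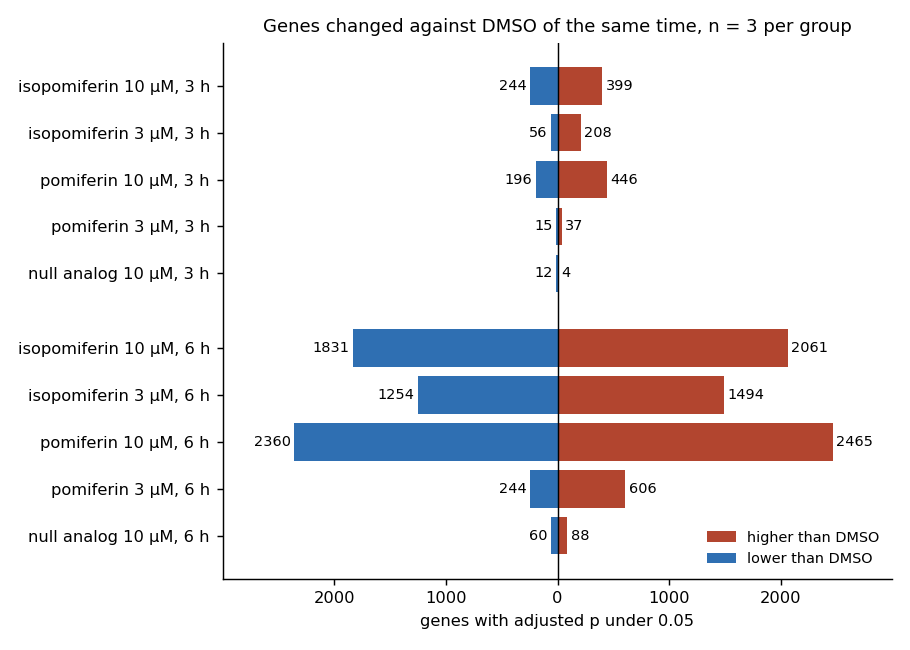
Number of genes past the adjusted p threshold in the TruSeq experiment (x axis, genes) for each treatment against DMSO of the same time (y axis), with genes that fell to the left of 0 and genes that rose to the right. Pomiferin at 10 µM for 6 h has the longest bars (2465 up, 2360 down) and the null analog at 3 h the shortest (4 up, 12 down).

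Further gene groups moved in part with isopomiferin at 6 h. Of 22 immediate early and MAPK feedback genes 16 rose, among them IER3 (1.16 ± 0.09) and ETV5 (0.98 ± 0.08). Of 22 hypoxia and glycolysis genes 12 rose and 3 fell, with the growth factor VEGFA at 1.95 ± 0.11. Of 19 lysosome and autophagy genes 10 rose and 1 fell, with the autophagy receptor SQSTM1 at 1.20 ± 0.10, and of 15 FOXO and PI3K feedback genes 7 rose and 1 fell. Heat shock genes rose in 7 of 15 cases, for example the chaperone HSPA8 by 0.60 ± 0.06. Of 21 gene lists 13 passed the camera set test, and 12 of those held with an estimated correlation between genes; heat shock was lost (adjusted p = 0.137 with an estimated correlation). The lists for MYC targets (1 up and 2 down of 22), the mesenchymal state (7 up and 3 down of 18), p53 targets (5 up and 3 down of 21), the aryl hydrocarbon receptor (2 up and 3 down of 8), metallothioneins (1 up of 7), YAP and TEAD targets (4 up and 3 down of 17) and markers of other cell types (1 up of 15) did not pass. The mitochondrially encoded list did not pass either, with 0 of 13 genes called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05.

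Pomiferin at 10 µM for 6 h raised the same 24 ATF4 and 17 unfolded protein response genes, raised heat shock genes and lowered MYCN. CHAC1 rose by 5.10 ± 0.25, INHBE by 5.19 ± 0.30, GDF15 by 4.88 ± 0.23 and the stress factor ATF3 by 3.79 ± 0.19, and HSPA5 by 2.03 ± 0.07. Of 15 heat shock genes 12 rose and 1 fell. The inducible chaperone genes HSPA1A (1.75 ± 0.09) and HSPA1B (1.65 ± 0.07), near-identical copies between which reads cannot be split with certainty, rose most, and their co-chaperone BAG3 rose by 1.28 ± 0.07. MYCN fell by 0.64 ± 0.05, from 3778 to 2426 CPM (adjusted p = 1.53e-12), and TEAD4, a partner of YAP, by 0.41 ± 0.09. Of 22 cholesterol biosynthesis genes 12 fell and 1 rose (13 and 2 adjusted over the list alone), with the squalene synthase FDFT1 at −0.69 ± 0.05 and INSIG1 at −0.57 ± 0.06. NRF2 genes rose in 16 of 19 cases, with HMOX1 at 2.85 ± 0.11. Of 20 adrenergic genes 14 fell and 2 rose, with HAND1 at −0.56 ± 0.05, and of 24 G2 and mitosis genes 20 fell. In total 4825 genes passed, 2465 up and 2360 down, and 457 changed at least 2-fold; 42.5% of genes had separate groups, against 10% by chance. Of 15 lists that passed, 12 held with an estimated correlation; those lost were MYC targets (8 down of 22; adjusted p = 0.148), S phase (3 up and 12 down of 22; adjusted p = 0.148) and FOXO (7 up and 1 down of 15; adjusted p = 0.0638). Without replicate 2 the count was 3128.

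The null analog at 10 µM for 6 h lowered cholesterol biosynthesis genes. INSIG1 fell by 1.95 ± 0.06, from 52.1 ± 1.67 to 13.5 ± 1.5 CPM (SD, n = 3 each), the sterol oxidase MSMO1 by 1.60 ± 0.09, the synthase HMGCS1 by 1.54 ± 0.08 and FDFT1 by 1.11 ± 0.05. In all, 20 of 22 members of the list fell (21 adjusted over the list alone), and the set test gave an adjusted p of 5.71e-22 with an estimated correlation. The largest rises were those of ANKRD1, a YAP target (1.02 ± 0.15), MALL (0.96 ± 0.14) and SH3TC1 (0.91 ± 0.15). Of 22 immediate early genes 4 rose (10 adjusted over the list alone), with SPRY2 at 0.42 ± 0.08, and the set test held with an estimated correlation (adjusted p = 0.0209). Neither the 24 ATF4 nor the 17 unfolded protein response genes held a call by edgeR or by DESeq2; at an unadjusted p under 0.05, 0 and 1 of them rose. MYCN was at −0.15 ± 0.05 (adjusted p = 0.139). The test called 148 genes, 88 up and 60 down, and 13 changed at least 2-fold; 17.2% of genes had separate groups, against 10% by chance. Without replicates 1, 2 and 3 in turn it called 66, 40 and 59. SH3TC1 did not pass without replicate 2 (0.81) nor SPRY2 without replicates 2 and 3 (0.45 and 0.38), while MYCN passed in a fit of the compared groups alone (−0.16). With an estimated correlation the set tests for the adrenergic, unfolded protein response, heat shock, S phase, aryl hydrocarbon receptor and YAP lists were lost (adjusted p = 0.38, 0.396, 0.0896, 0.0877, 0.109 and 0.0718).

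**Figure D2:**
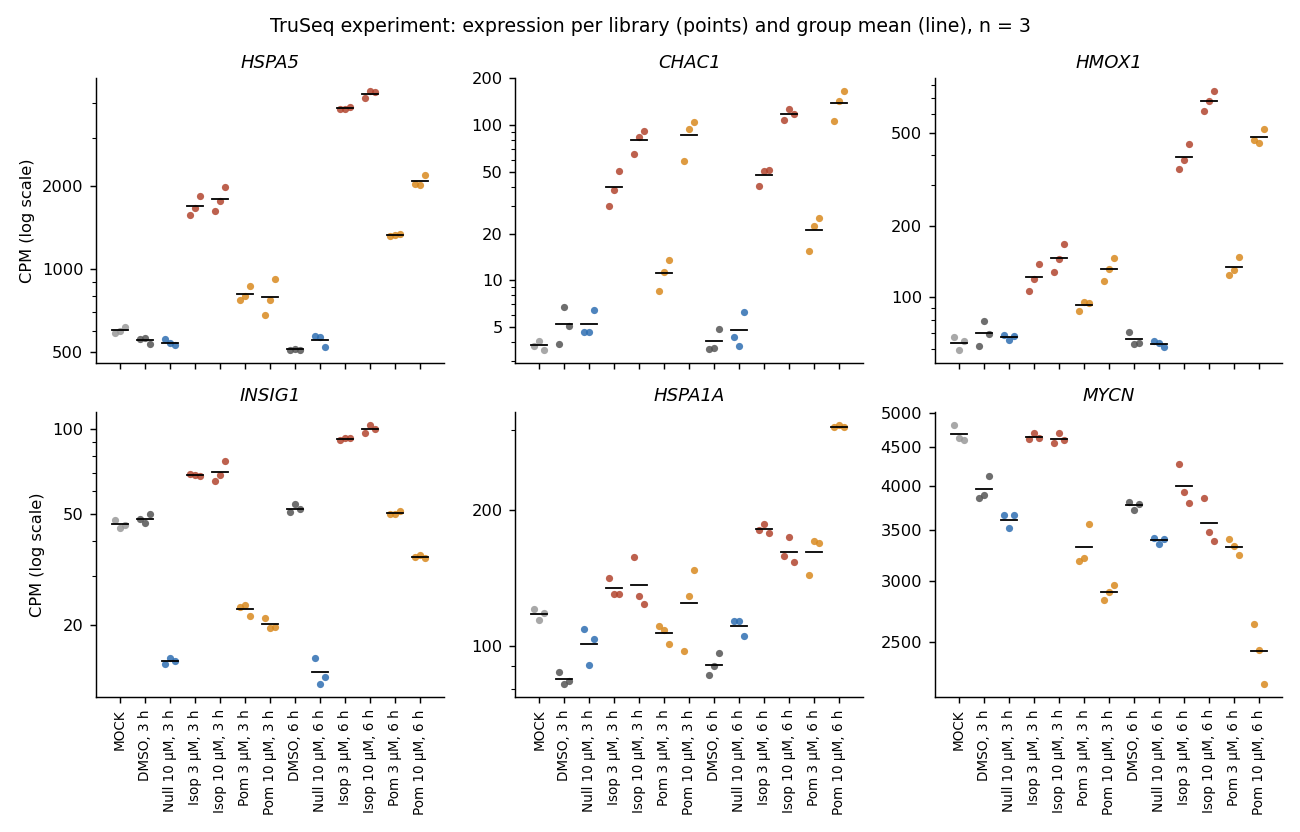
CPM (y axis, log scale) of HSPA5, CHAC1, HMOX1, INSIG1, HSPA1A and MYCN in the TruSeq libraries by treatment and time (x axis), one point per library and a line at each group's mean. HSPA5 at 6 h has a mean of 4328 CPM with isopomiferin at 10 µM against 513 in DMSO, and INSIG1 lies at 13.5 with the null analog against 52.1 in DMSO.

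The null analog served as the inactive relative, so each isoflavone was also set against it at 10 µM and 6 h. Pomiferin exceeded it most for INHBE (5.55 ± 0.29), CHAC1 (4.85 ± 0.24) and the growth inhibitor DDIT4 (4.84 ± 0.18), and fell below it for CCDC177 (−1.73 ± 0.19), FAM30A (−1.67 ± 0.20) and the neural factor POU3F2 (−1.39 ± 0.13). All 24 ATF4 and 17 unfolded protein response genes were higher with pomiferin, as were 19 of 22 cholesterol biosynthesis genes. MYCN was lower by 0.49 [0.39 to 0.59] (log2, 95% interval), and of 20 adrenergic genes 11 were lower and 2 higher. Isopomiferin exceeded the null analog for all 22 cholesterol genes, with INSIG1 at 2.90 [2.78 to 3.01], while the MYCN difference was 0.08 [−0.03 to 0.18] (adjusted p = 0.29). Between pomiferin and the null analog 4589 genes differed, and between isopomiferin and the null analog 3901. Of the lists, 14 and 13 passed, and with an estimated correlation the mesenchymal list was lost for pomiferin (adjusted p = 0.0523) and S phase for isopomiferin (adjusted p = 0.121). The aryl hydrocarbon receptor list passed upwards for pomiferin although its median lay below 0 (−0.05). That list shares SLC7A5 with the ATF4 list, whose members were all higher with pomiferin, so this result does not stand for the receptor alone. Without replicate 2 the isopomiferin count was 2411.

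In structure, isopomiferin is pomiferin with a prenyl group closed onto the neighbouring hydroxyl. At 10 µM and 6 h they differed in endoplasmic reticulum, sterol, heat shock and MYCN expression, and in part of the ATF4 genes. HSPA5 was higher with isopomiferin by 1.05 [0.91 to 1.19] (log2, 95% interval, n = 3 per group), and 15 of 17 unfolded protein response genes were higher (16 adjusted over the list alone). Cholesterol biosynthesis genes were higher in 20 of 22 cases, with INSIG1 at 1.52 [1.42 to 1.63] and HMGCS1 at 1.13 [0.99 to 1.28]. MYCN was higher with isopomiferin by 0.56 [0.46 to 0.66]. Heat shock genes were lower with isopomiferin in 9 of 15 cases, HSPA1A at −0.92 ± 0.09 (SE), and HAND1 was lower by 0.48 [0.39 to 0.58]. For CHAC1 the difference was −0.23 [−0.55 to 0.08] (adjusted p = 0.361) and for SLC7A11 −0.13 [−0.35 to 0.10] (adjusted p = 0.512; 0.00 without replicate 1), while DDIT3 was higher by 0.42 [0.25 to 0.59] and HMOX1 by 0.52 [0.33 to 0.70]. Of 24 ATF4 genes 3 were higher and 4 lower. The compounds differed in 1952 genes, and without replicate 1 or replicate 2 in 1108 or 711.

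The compounds already differed at 3 h. At 10 µM, CHAC1 rose by 3.91 ± 0.28 with isopomiferin and 4.02 ± 0.27 with pomiferin, a difference of −0.11 [−0.46 to 0.23] (adjusted p = 0.868). HSPA5 rose by 1.70 ± 0.07 and 0.53 ± 0.07. INSIG1 rose by 0.54 ± 0.05 with isopomiferin but was at −1.26 ± 0.06 with pomiferin and −1.69 ± 0.07 with the null analog. MYCN rose by 0.22 ± 0.05 with isopomiferin (adjusted p = 0.00433; 0.20 without replicate 2 and 0.22 in a fit of those groups alone, not passing in either) and fell by 0.45 ± 0.05 with pomiferin (adjusted p = 8.36e-08). The ATF4 list rose in 19 and 20 of 24 members with isopomiferin and pomiferin, and the unfolded protein response list in 14 and 11 of 17. The cholesterol list rose in 6 members with isopomiferin and fell in 9 with pomiferin and 10 with the null analog, of 22. The counts were 643, 642 and 16 genes for isopomiferin, pomiferin and the null analog, and 372 between the isoflavones. Without replicate 2 these were 193, 200, 10 and 87, and without replicate 3 342, 337, 11 and 164; without replicate 1 pomiferin gave 382 and the pair 233. Of 13, 13 and 3 lists that passed, 11, 8 and 2 held with an estimated correlation; heat shock and lysosome were lost for isopomiferin (adjusted p = 0.17 and 0.0979), adrenergic, mesenchymal, heat shock, YAP and FOXO for pomiferin (adjusted p = 0.137, 0.0664, 0.367, 0.0664 and 0.137) and the aryl hydrocarbon receptor for the null analog (adjusted p = 0.0603).

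The 2 doses of each isoflavone were compared gene by gene. Isopomiferin at 3 µM already raised HSPA5 by 2.90 ± 0.07 at 6 h, and 10 µM added 0.18 [0.04 to 0.31] (adjusted p = 0.139; passing in a fit of those groups alone, 0.17), while CHAC1 gained 1.31 [0.96 to 1.66] and GDF15 2.34 [2.07 to 2.60] between the doses. With pomiferin, HSPA5 rose by 1.38 ± 0.07 at 3 µM and gained 0.65 [0.51 to 0.79], CHAC1 gained 2.72 [2.33 to 3.11] and HSPA1A 0.93 ± 0.09 (SE). INSIG1 was at −0.06 ± 0.05 with 3 µM of pomiferin (adjusted p = 0.629) and lower by 0.52 [0.40 to 0.63] with 10 µM, and MYCN was lower by a further 0.46 [0.36 to 0.56]. Between the doses 776 genes differed for isopomiferin and 2695 for pomiferin at 6 h, and 44 and 165 at 3 h. At 3 µM against DMSO, isopomiferin changed 2748 genes at 6 h and 264 at 3 h, and pomiferin 850 and 52. Without replicates 1, 2 and 3 in turn the counts between doses were 375, 230 and 196 for isopomiferin and 1657, 1428 and 1938 for pomiferin at 6 h, and 22, 1 and 7 and 132, 31 and 52 at 3 h. At 3 µM they were 1899, 1404 and 1938 (6 h) and 135, 70 and 102 (3 h) for isopomiferin, and 508, 345 and 372 and 31, 14 and 20 for pomiferin.

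Isopomiferin and pomiferin changed many of the same genes. At 6 h and 10 µM, 1533 genes rose with both isopomiferin and pomiferin where independent lists would share 331.4, 1204 fell with both (281.9 if independent) and 35 moved in opposite directions. Across all genes the log2 changes correlated at 0.685, against 0.495 in simulated counts with no treatment effect and the same DMSO libraries; genes are not independent replicates, so no p is given. The lists are not independent, because the same 3 DMSO libraries serve each of them. The null analog shared 68 rises with pomiferin (14.15 if independent) and 36 falls (9.237), INSIG1 and FDFT1 among the falls, with 7 genes in opposite directions. With isopomiferin it shared 68 rises (11.83) and 20 falls (7.167), while 26 genes went opposite ways. Its correlations of 0.347 with pomiferin and 0.362 with isopomiferin lay below the 0.506 and 0.505 of the simulated counts, and their covariances above the simulated ones by 0.0371 and 0.0373, so the correlations do not separate a shared response from shared controls. The effect at 6 h differed from that at 3 h for 844 genes with isopomiferin, 1787 with pomiferin and 5 with the null analog. Among those 5 are the sterol genes SREBF2 (−0.52), FDFT1 (−0.68), HMGCS1 (−0.68) and DHCR7 (−0.59), each lower at 6 h and named after their values were seen. Without replicate 2 the counts were 279, 760 and 2, without replicate 3 462, 1177 and 3, and without replicate 1 pomiferin gave 911. DMSO at 6 h against mock-treated cells, whose time labels conflict, differed in 1206 genes, with MYCN at −0.31 ± 0.05 (adjusted p = 0.00015) and HSPA1A at −0.37 ± 0.10, and DMSO at 3 h in 72. Those counts were 154 and 8 without replicate 2, 229 and 14 without replicate 3, and the second was 396 without replicate 1. MYCN did not pass without replicate 2 (−0.31), nor HSPA1A without replicates 2 and 3 (−0.39 and −0.41).

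The third experiment tested whether structural relatives of isopomiferin and known CK2 inhibitors change expression as isopomiferin does. At 24 h, isopomiferin at 15 (no unit given) raised the stress genes NUPR1 (5.53 ± 0.40), GDF15 (5.27 ± 0.37), ADM2 (5.25 ± 0.23) and TRIB3 (4.57 ± 0.27) on the log2 scale (SE, n = 3 against 9 DMSO wells), with HMOX1 at 4.20 ± 0.28 and HSPA5 at 2.39 ± 0.16. MYCN fell by 1.53 ± 0.39, from 540 ± 192 to 187 ± 72.7 CPM (SD; adjusted p = 0.002). The retinoic acid binding gene CRABP2 (−2.90 ± 0.27) and the kinase gene MAP2K6 (−2.59 ± 0.56) had the largest falls, and the adrenergic factor PHOX2A (−1.60 ± 0.23) fell too. The ATF4 list rose in 22 of 23 genes, the unfolded protein response in 17 of 17 and NRF2 in 13 of 20. Of 24 G2 and mitosis genes 20 fell, of 21 MYC targets 15, of 20 adrenergic genes 12, and of 21 cholesterol genes 7 rose. Among quality lists, 9 of 13 mitochondrially encoded genes fell, with MT-ND4 at −0.61 ± 0.10, as did 4 of 10 markers of other cell types, with COL1A1 at −0.84 ± 0.17. CSNK2A1 was at 0.17 ± 0.20 (adjusted p = 0.618), CSNK2A2 at 0.50 ± 0.21 (adjusted p = 0.0862) and CSNK2B at −0.07 ± 0.17 (adjusted p = 0.845; 0.04 without replicate 2). In all 3113 of 15596 genes passed, 1740 of them changed at least 2-fold, and 14.7% had separate groups against 0.909% by chance. Without replicate 1 or 2 the count was 2040 or 1882, without replicate 1 the falls were 10 among G2 and mitosis genes and 4 among mitochondrially encoded ones, without replicate 2 those among adrenergic genes were 8, and without replicate 2 MYCN did not pass (−1.09).

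Pomiferin at 10 in the third experiment changed more genes than any other treatment there. FGF19, a growth factor induced by ATF4, rose by 6.78 ± 0.49, the chaperone gene HSPA1A by 6.31 ± 0.25, from 22.6 to 1796 CPM, the cell-cycle inhibitor CDKN1A by 5.64 ± 0.30 and HSPA5 by 4.20 ± 0.16. MYCN fell by 2.54 ± 0.42 (adjusted p = 8.37e-07), and MYC, its relative, rose by 4.82 ± 0.41. The imprinted gene PEG10 (−4.40 ± 0.43), PHOX2A (−3.88 ± 0.31) and the somatostatin receptor SSTR2 (−3.47 ± 0.62) were among the largest falls. Heat shock genes rose in 12 of 15 cases, with DNAJB1 at 4.58 ± 0.15, ATF4 genes in 20 of 23 and unfolded protein response genes in 17 of 17. Of 24 G2 and mitosis genes 23 fell, of 22 ribosome biogenesis genes 17 and of 20 adrenergic genes 16. Of the CK2 genes, CSNK2A2 rose by 1.28 ± 0.20 and CSNK2A1 by 0.83 ± 0.20. Of quality lists, 6 of 13 mitochondrially encoded genes and 5 of 10 markers of other cell types fell. The total was 4915 genes, 2566 up and 2349 down, 3388 of them at least 2-fold, with 23.5% separate groups. Without replicate 2, 3 of the mitochondrially encoded genes fell, and without replicate 3, 11 of the ribosome biogenesis genes.

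**Figure D3:**
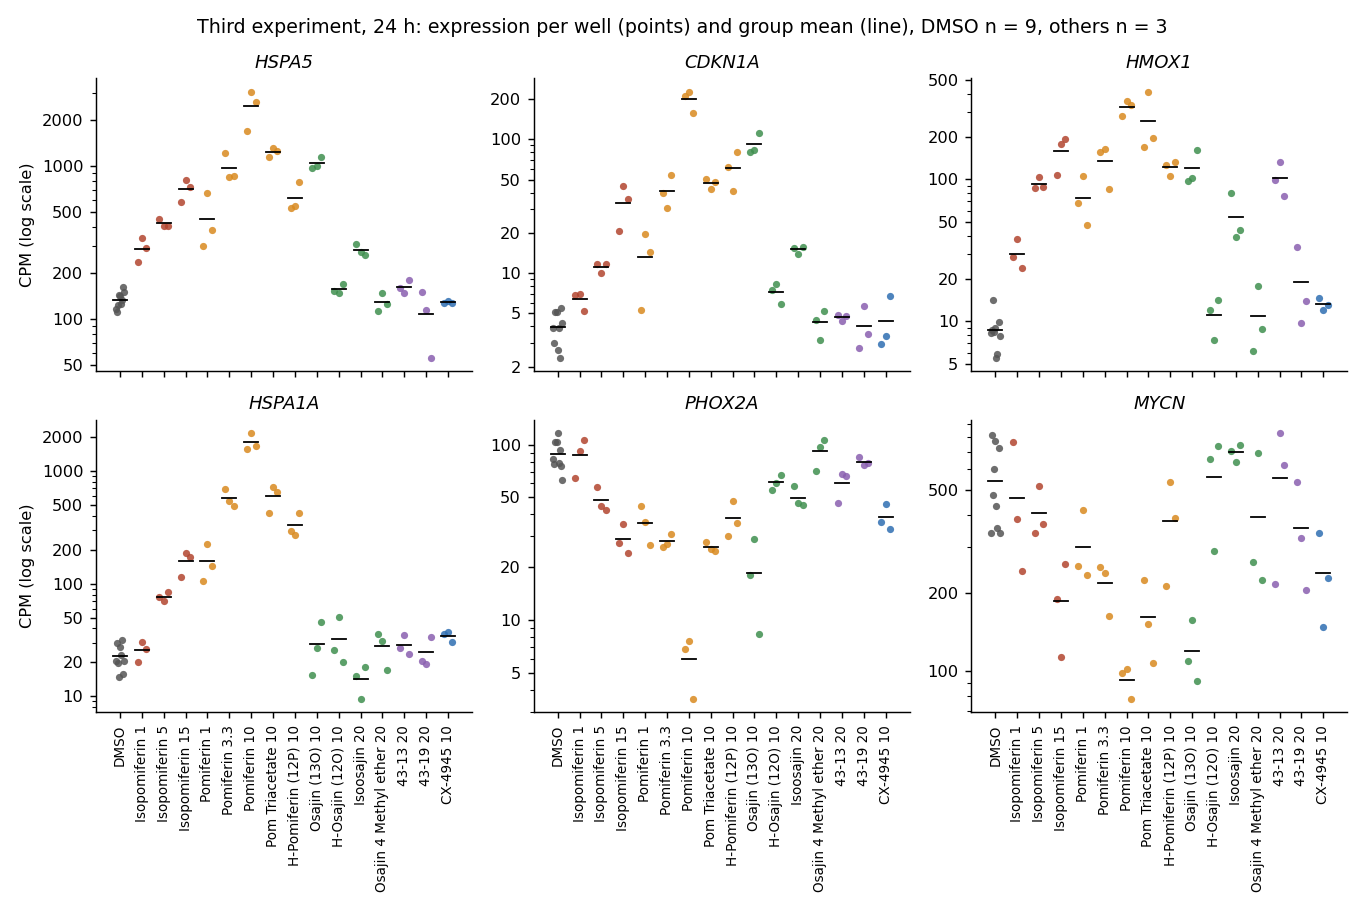
CPM (y axis, log scale) of HSPA5, CDKN1A, HMOX1, HSPA1A, PHOX2A and MYCN in wells of the third experiment by treatment (x axis), one point per well and a line at each group's mean. HSPA1A has a mean of 1796 CPM with pomiferin at 10 against 22.6 in DMSO.

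Relatives at the same dose were compared in pairs to set gene groups against parts of the molecule. Pomiferin carries 1 more hydroxyl than osajin, and at 10 it exceeded osajin for heat shock genes, by 5.97 [5.19 to 6.75] for HSPA1A and 4.68 [4.23 to 5.14] for DNAJB1 (log2, 95% interval, n = 3 against 3), with 12 of 15 members higher. HMOX1 was higher by 1.43 [0.74 to 2.12] and HSPA5 by 1.24 [0.83 to 1.66], while DDIT3 differed by 0.38 [−0.07 to 0.84] (adjusted p = 0.358) and MYCN by −0.37 [−1.27 to 0.53] (adjusted p = 0.712). Against DMSO, osajin raised DDIT3 by 4.31 ± 0.18 and HSPA5 by 2.96 ± 0.15, with HSPA1A at 0.34 ± 0.30 (adjusted p = 0.449; −0.14 without replicate 3). Pomiferin also exceeded its triacetate, in which the hydroxyls are acetylated, for HSPA1A (1.58 [0.96 to 2.20]) and HSPA5 (0.99 [0.57 to 1.40]), while DDIT3 differed by 0.53 [0.07 to 0.98] (adjusted p = 0.236) and HMOX1 by 0.32 [−0.35 to 0.99]. It exceeded H-pomiferin, whose structure the labels do not give, for HSPA1A (2.44 [1.80 to 3.09]), HSPA5 (1.98 [1.56 to 2.41]) and DDIT3 (1.25 [0.78 to 1.71]), and MYCN was at −2.03 [−2.94 to −1.13]. The pairs differed in 1055, 391 and 1002 genes; without replicates 1, 2 and 3 in turn osajin gave 572, 416 and 588, the triacetate 155, 108 and 243, and H-pomiferin 385, 428 and 537. Without replicate 2 HMOX1 against osajin (1.26) and HSPA5 against the triacetate (0.82) did not pass, and without replicate 3 MYCN against H-pomiferin (−1.92).

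Among the osajin relatives, osajin at 10 exceeded H-osajin for DDIT3 by 4.40 [3.86 to 4.94], HSPA5 by 2.74 [2.30 to 3.18] and HMOX1 by 3.42 [2.61 to 4.23], and the replication factor PCNA was at −2.31 [−2.81 to −1.82]. Of 23 ATF4 genes 22 were higher, MYCN was at −2.23 [−3.14 to −1.33], and HSPA1A at −0.17 [−0.88 to 0.55], but at 0.33 without replicate 2. Isoosajin at 20 exceeded the 4-methyl ether of osajin for TRIB3 by 4.03 [3.22 to 4.84], DDIT3 by 2.13 [1.62 to 2.63] and HMOX1 by 2.30 [1.50 to 3.09], with MYCN at 0.83 [−0.03 to 1.68] (adjusted p = 0.381). At 1, isopomiferin lay below pomiferin for HSPA1A (−2.63 [−3.31 to −1.95]), DDIT3 (−1.66 [−2.15 to −1.18]) and the AP-1 gene FOSL1 (−1.81 [−2.36 to −1.25]), and above it for PHOX2A (1.28 [0.76 to 1.80]). The relatives 43-13 and 43-19 at 20 differed in HMOX1 by 2.42 [1.66 to 3.18] (adjusted p = 5.03e-05), and 43-13 raised 12 of 20 NRF2 genes over DMSO (7 without replicate 2). The counts were 2665, 472, 184 and 33 genes. Without replicate 1 they were 1540, 182, 84 and 26, without replicate 2 1868, 251, 25 and 9, and without replicate 3 1605, 249, 68 and 25. HMOX1 did not pass for isoosajin without replicate 1 (1.62) or for 43-13 without replicate 2 (1.92), nor at 1 FOSL1 without replicate 2 (−1.55) or PHOX2A without replicates 2 and 3 (1.25 and 0.95).

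CX-4945 (silmitasertib), a CK2 inhibitor, raised most ATF4 genes and few unfolded protein response genes. At 10 against DMSO it raised 19 of 23 ATF4 genes, TRIB3 by 2.46 ± 0.34 and DDIT3 by 1.62 ± 0.19; of 17 unfolded protein response genes 3 rose and 1 fell. It lowered 11 of 21 cholesterol genes. HSPA5 was at −0.06 ± 0.18 (adjusted p = 0.863; 0.01 with DESeq2 size factors) and HMOX1 at 0.62 ± 0.37 (adjusted p = 0.268), while MYCN fell by 1.18 ± 0.38 (adjusted p = 0.0212). Against pomiferin at the same dose, all 17 unfolded protein response genes were lower, HSPA5 at −4.26 [−4.73 to −3.79] and HMOX1 at −4.62 [−5.45 to −3.79], and 21 of 24 G2 and mitosis genes were higher. CX-4945 changed 2654 genes against DMSO, and 3559 differed from pomiferin. With separate DMSO wells for each side, the log2 changes of pomiferin at 10 correlated across genes at 0.465 with its triacetate, 0.435 with osajin, 0.427 with isopomiferin at 15, 0.406 with H-pomiferin, 0.177 with CX-4945 at 10 and −0.014 with the 4-methyl ether. The relative isoosajin gave 0.216. Among treatments that are not relatives of isopomiferin, PF-47776 at 1.6 gave 0.185, JQ1 at 10 gave 0.134 and NVP-BEZ-235 gave 0.115. Palbociclib gave 0.102, flavopiridol 0.04, dasatinib −0.013 and CX-4945 at 3.3 gave 0.053. CX-4945 at 10 thus lay below PF-47776 and above the others of these. Without replicates 1 and 2 in turn CX-4945 gave 1661 and 1624 genes, and against pomiferin 2193 without replicate 2. MYCN did not pass with a block for the replicate number (−1.10) or without replicates 2 and 3 (−0.76 and −1.26).

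The estimates for HSPA1A and HSPA5 were larger at each higher dose of both isoflavones in the third experiment, where the doses were not tested against each other. Pomiferin at 1, 3.3 and 10 moved HSPA1A by 2.82, 4.68 and 6.31, HSPA5 by 1.76, 2.86 and 4.20, and MYCN by −0.83 (adjusted p = 0.176), −1.31 and −2.54. Isopomiferin at 1, 5 and 15 moved HSPA5 by 1.1, 1.65 and 2.39, HMOX1 by 1.80, 3.43 and 4.20, and HSPA1A by 0.19 (adjusted p = 0.922), 1.77 and 2.81. The counts for pomiferin were 1135, 2938 and 4915 genes, and for isopomiferin 223, 1064 and 3113. Without replicates 1, 2 and 3 in turn pomiferin at 1 gave 753, 424 and 762 and at 3.3 1873, 1904 and 2407, and isopomiferin at 1 gave 111, 88 and 128 and at 5 594, 608 and 600. MYCN passed at 1 of pomiferin with low-count genes kept (−0.85) and did not pass at 3.3 without replicate 3 (−1.24).

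The second experiment asked how the leading compounds act over time and dose. Isopomiferin at 10 for 24 h raised TRIB3 by 6.68 ± 0.44, HMOX1 by 6.56 ± 0.28, from 7.76 to 746 CPM, HSPA5 by 2.71 ± 0.17 and HSPA1A by 3.92 ± 0.21 (SE, n = 3 against 6 control wells). MYCN fell by 1.59 ± 0.39, from 906 ± 248 to 300 ± 77.9 CPM (SD; adjusted p = 0.0011), and CRABP2 (−2.93 ± 0.23), MAP2K6 (−4.40 ± 0.70) and the noradrenaline transporter SLC6A2 (−3.04 ± 0.40) were among the largest falls. ATF4 genes rose in 22 of 23 cases, unfolded protein response genes in 17 of 17 and NRF2 genes in 13 of 19. Of 19 adrenergic genes 14 fell, of 24 G2 and mitosis genes 18 and of 20 MYC targets 12. Markers of other cell types fell in 2 of 8 cases. In all 2112 of 11539 genes passed, 1143 up and 969 down, with 20.2% separate groups against 2.38% by chance. At 3.3 for 24 h the count was 357, and at 6 h 149 at 10 and 60 at 3.3. At 6 h and 10 MYCN was at −1.32 ± 0.36 (adjusted p = 0.039), and did not pass without replicate 2 (−0.82) or 3 (−1.39). Without replicates 1, 2 and 3 in turn the counts at 10 were 1269, 1417 and 1408 at 24 h and 80, 75 and 69 at 6 h, and those at 3.3 were 139, 139 and 214 and 41, 35 and 41. The falls at 10 and 24 h were 11 of 24 G2 and mitosis genes without replicate 2 or 3, and 8 of 20 MYC targets without replicate 1. The labels of this experiment give doses in mM, the study's summary in µM.

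In the first experiment isopomiferin at 15 (no unit given) had 1 well on each of 2 plates. HMOX1 rose by 6.27 ± 0.31, from 5.57 to 446 CPM, ADM2 by 6.97 ± 0.34, DDIT3 by 4.27 ± 0.23, HSPA5 by 2.70 ± 0.20 and HSPA1A by 3.40 ± 0.29 (SE, n = 2 against 8 DMSO wells). GDF15 had no count in any DMSO well and stood at 62.1 ± 60.5 CPM with isopomiferin. HAND1 fell by 1.68 ± 0.25, with the adrenergic granule gene CHGA at −1.16 ± 0.18 and the replication gene MCM3 at −1.41 ± 0.19. MYCN was at −0.14 ± 0.62 (adjusted p = 0.926; 0.41 without replicate 2). ATF4 genes rose in 22 of 24 cases, unfolded protein response genes in 14 of 16 and NRF2 genes in 13 of 18, and G2 and mitosis genes fell in 12 of 24. Without replicate 1 the G2 and mitosis falls were lost (0 of 24), and 12 of 23 ATF4, 5 of 16 unfolded protein response and 9 of 18 NRF2 genes rose; without replicate 2, 9 of the 24 fell and 18, 14 and 12 rose. Of 8 markers of other cell types 2 fell, COL1A1 (−1.31 ± 0.24) and DCN (−3.26 ± 0.83), and 1 rose, CDH1 (1.81 ± 0.54). DCN did not pass without replicate 1 or 2 (−2.80 and −3.37), nor CDH1 there (2.43 and 1.13) or without the plate as a block (1.86). In all 1709 of 13438 genes passed, 967 up and 742 down, 1338 of them at least 2-fold, and both treated wells lay on one side of all 8 controls for 15% of genes, against 4.44% by chance. With DESeq2 size factors in place of trimmed means the median of all genes moved from −0.0744 to 0.0501. Without replicate 1 or 2, where the lone well is taken to vary like the other groups, the count was 416 or 958, and without the plate as a block 877, with MCM3 (−1.39) not passing.

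The log2 changes under isopomiferin correlated between the 4 experiments, least for the second experiment at 6 h. Between the second experiment at 24 h and the third, log2 changes correlated across genes at 0.571, and 681 genes rose in both (129.1 if independent), 504 fell in both (96.79) and 4 went opposite ways. The first experiment correlated at 0.565 with the second at 24 h and 0.521 with the third. TruSeq at 6 h correlated at 0.331 with the second experiment at 6 h, 0.476 with it at 24 h, 0.377 with the third and 0.430 with the first. The second experiment at 6 h correlated at 0.236 with the third, 0.202 with the first and 0.19 with its own 24 h. Among genes with a mean of at least 30 CPM in both, those last 3 values were 0.54, 0.441 and 0.456, and the other correlations ran from 0.636 to 0.862. With a replicate left out all the correlations over all genes were lower: TruSeq gave 0.243 to 0.262 with the second at 6 h, 0.399 to 0.419 at 24 h, 0.285 to 0.33 with the third and 0.267 to 0.335 with the first. The second at 24 h gave 0.47 to 0.489 with the third and 0.377 to 0.461 with the first, and those 2 gave 0.377 to 0.42. The second at 6 h gave 0.166 to 0.181 with the third, 0.134 to 0.139 with the first and 0.136 to 0.156 with its own 24 h. HSPA5, DDIT3, TRIB3 and HMOX1 rose in each of the 4 experiments. MYCN fell by 1.53 ± 0.39 and 1.59 ± 0.39 at 24 h in the third and second, and did not pass at 24 h in the first or at 6 h with TruSeq. In the second at 6 h and 10 it was at −1.32 and passed, against −0.08 with TruSeq at 6 h. With TruSeq at 3 h and 10 µM MYCN rose by 0.22 and passed. Neither of these calls held with each replicate left out in turn, so the experiments do not give a single time course.

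**Figure D4:**
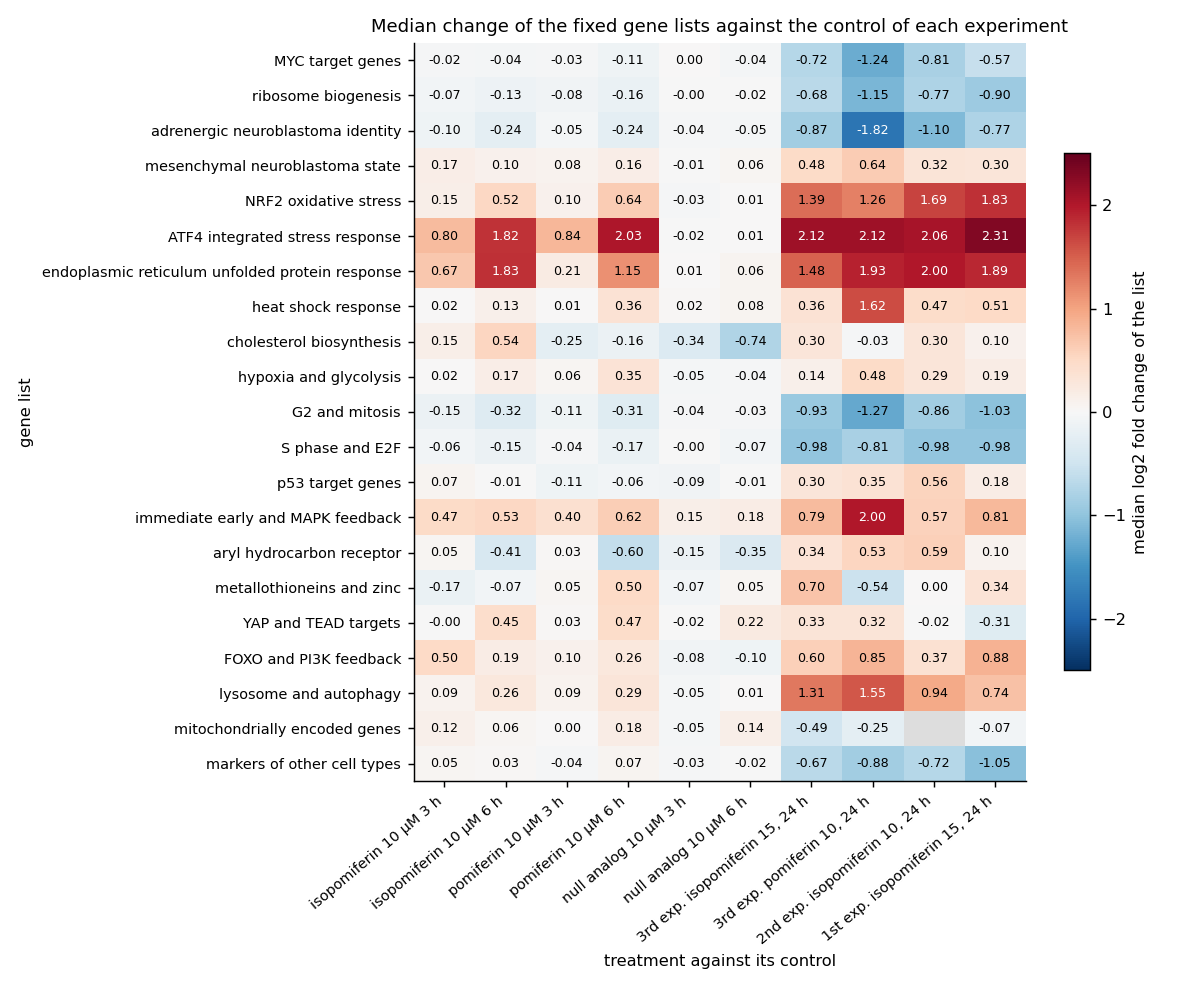
Median log2 change (colour and printed value) of each fixed gene list (y axis) for each treatment against its control (x axis), with a grey cell where no member was measured. The ATF4 list has a median of 1.82 with isopomiferin and 2.03 with pomiferin at 6 h in the TruSeq experiment, and 0.01 with the null analog.

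Known drug classes were among the 90 compounds of the first experiment; their genes were picked after the values were seen, and no class was tested against another. Daunorubicin at 3, a topoisomerase poison, lowered the cyclin genes CCNB1 (−2.87 ± 0.35) and CCNB2 (−2.27 ± 0.43; not passing without the plate as a block, −2.13) and the adrenergic factor HAND1 (−2.14 ± 0.28), and raised ATF3 (4.16 ± 0.41) and DDIT3 (3.24 ± 0.27; SE, n = 2 against 8). The cardiac glycosides proscillaridin A and digitoxin at 0.15 raised PPP1R15A (3.85 ± 0.26 and 3.19 ± 0.27), ARC (3.40 ± 0.25 and 1.88 ± 0.28) and TXNIP (2.84 ± 0.37 and 2.88 ± 0.35), and lowered HSPA8 (−3.33 ± 0.35 and −2.85 ± 0.32). Proscillaridin A lowered DDC, an enzyme of catecholamine synthesis (−3.48 ± 0.64). Of 24 G2 and mitosis genes 17 and 15 rose with them, but 8 and 4 without replicate 1 and 8 with each without replicate 2. In the same wells 9 and 8 of 13 mitochondrially encoded genes, a list read for RNA quality, fell, and 1 rose with proscillaridin A. Homidium bromide at 7.5 and proflavine at 5, both DNA intercalators, lowered 10 and 10 of 13 mitochondrially encoded genes, and homidium bromide raised 1. MT-ND2 was at −2.79 ± 0.20 and −1.61 ± 0.19. Homidium bromide also lowered the sterol gene DHCR7 (−2.96 ± 0.49) and the ribonucleotide reductase gene RRM2 (−2.02 ± 0.32). NSC255109 at 7.5 raised HSPA8 (1.91 ± 0.21) and HSP90AA1 (1.75 ± 0.23). Daunorubicin changed 3172 genes, proscillaridin A 3026, digitoxin 2322, proflavine 2599, homidium bromide 1576 and NSC255109 1523. Without replicate 1 these were 819, 1031, 386, 770, 233 and 320, and without replicate 2 1431, 1055, 1334, 536 and 447 from proscillaridin A onwards. Without the plate as a block HSPA8 did not pass for either glycoside (−3.20 and −2.76) or for NSC255109 (1.94). At least 50 genes changed with 44 compounds, and with all 90 when genes with low counts were kept. The compounds had a median of 41.5, and isopomiferin ranked 8. NSC73846 at 0.25 changed 0 genes by edgeR (602 at an unadjusted p under 0.05; no other tool was run). Wells without DMSO differed from DMSO wells in 7 genes, 1 without replicate 1 and 124 with low counts kept.

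**Figure D5:**
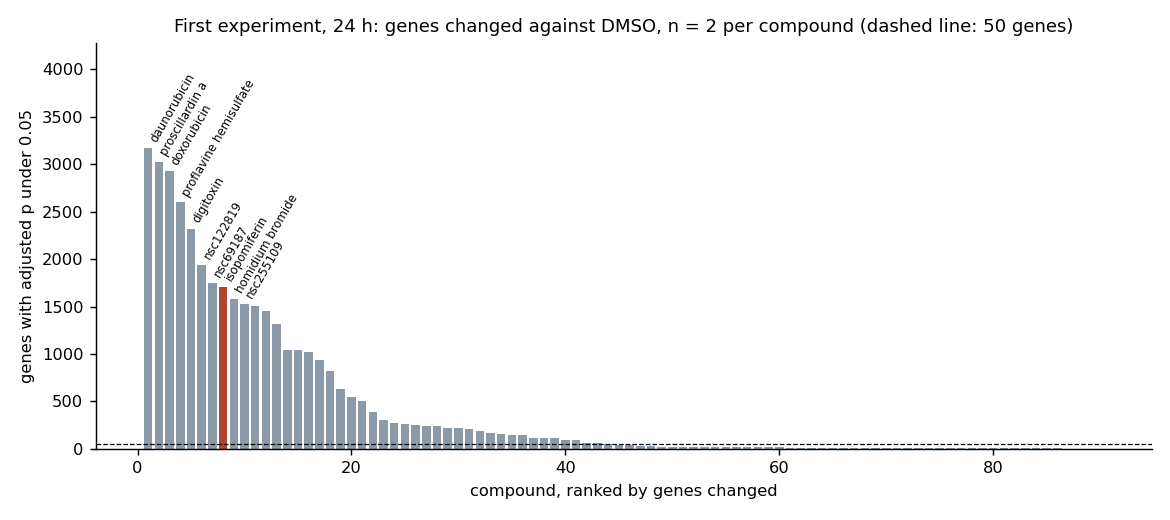
Number of genes past the adjusted p threshold (y axis) for each of the 90 compounds of the first experiment, ranked (x axis), with isopomiferin in red and a dashed line at 50 genes. Daunorubicin ranks 1 with 3172 genes and isopomiferin 8 with 1709.

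Other compounds of the second experiment were examined through single genes at 24 h and not tested against each other. NSC255109 at 2.5 raised the chaperone genes HSPA8 (2.11 ± 0.12) and HSP90AA1 (1.53 ± 0.17) and lowered SPRY4 (−4.61 ± 0.57) and NME1 (−1.61 ± 0.15; SE, n = 3 against 6). Podofilox at 1, which blocks microtubules, raised the YAP target ANKRD1 (3.50 ± 0.29) and CHAC1 (3.23 ± 0.26) and lowered HAND1 (−1.94 ± 0.24). NSC3905 at 3 raised the hypoxia genes NDRG1 (6.80 ± 0.28), PDK1 (4.07 ± 0.32) and VEGFA (3.61 ± 0.20). Narasin at 1, an ionophore, raised CHAC1 (4.04 ± 0.24) and the sterol gene INSIG1 (2.26 ± 0.26). NSC305798 at 5 raised HMOX1 (5.13 ± 0.30) and DDIT3 (4.18 ± 0.24) and lowered MYCN (−1.21 ± 0.37; −0.96 without replicate 2, not passing there or without replicate 3). In the first experiment NSC305798 at 5 (no unit given) changed only 5 genes at 24 h. In the second experiment NSC255109 changed 2118 genes, podofilox 1451, NSC3905 1444, narasin 1247 and NSC305798 951. Without replicates 1, 2 and 3 in turn the counts were 1279, 1199 and 1310, 884, 898 and 859, 816, 669 and 830, 678, 657 and 705 and 451, 417 and 609. At least 50 genes changed with 20 of 30 treatments at 24 h (median 169.5) and with 9 of 30 at 6 h (median 5). By edgeR 0 genes passed for NSC136037 at 0.25 at 24 h (722 at an unadjusted p under 0.05), and at 6 h for it at 0.25 (610) and 0.085 (667) and for Azure A at 1 (592). DESeq2 called 1 gene for Azure A and 0 for the others.

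Some gene lists moved in part or nearly whole with single compounds of the first and second experiments. These treatments were picked after their values were seen, and no chemical class was tested against the other compounds. Hydroxyquinolines and their esters, which bind metals, raised metallothionein and zinc genes, many of them near-identical copies between which reads cannot be split with certainty. Chloroxine at 15 and benzoxiquine at 7.5 raised 8 of 9, nitroxoline at 7.5, cloxyquin at 5 and broxaldine at 5 raised 7 each, and oxyquinoline at 3 raised 6. Disulfiram at 0.15, whose products also bind metals, raised 7. Without replicate 1 the counts were 7 for chloroxine and benzoxiquine, 6 for nitroxoline and 5 for the other 4. Suloctidil at 10, which is not a hydroxyquinoline, raised 7 and lowered 1, and raised 7 without either replicate. The rise was thus not confined to hydroxyquinolines and disulfiram. The quality list moved too: of 13 mitochondrially encoded genes 8 rose with disulfiram, 7 with oxyquinoline and 6 with benzoxiquine (6, 5 and 4 without replicate 1 and 8, 6 and 1 without replicate 2). In the second experiment cloxyquin at 5 raised 7 of 9 at 6 h and 8 at 24 h (DESeq2 called 5 of 9 and 3 of the 4 it tested). NSC3905 raised all 21 hypoxia and glycolysis genes at 5 in the first experiment (14 without replicate 1 and 16 without replicate 2), and at 3 in the second raised 19 of 20 at 6 h and all 20 at 24 h. Cerivastatin, a statin, raised 9 of 20 cholesterol biosynthesis genes at 5 and 10 at 1.7 after 24 h (6 at 1.7 without replicate 3). Of 24 ATF4 genes the ionophore gramicidin at 3 raised 23, the endoperoxide artesunate at 15 raised 21, and tioguanine at 1 and ivermectin at 10 raised 20 each. Of the metal-binding compounds above, chloroxine raised 21, broxaldine and nitroxoline 20 each and oxyquinoline 18. Artenimol at 15 and cetylpyridinium at 2 raised 19 each and podofilox at 2 raised 18. This response was thus not particular to isopomiferin, which raised 22. Without replicate 1 gramicidin, artesunate, tioguanine and ivermectin raised 14, 14, 13 and 12 of 23. Chloroxine, broxaldine, nitroxoline and oxyquinoline then raised 12, 10, 3 and 8, and artenimol, cetylpyridinium and podofilox 12, 13 and 11.

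The third experiment also held inhibitors with other targets, which were not tested against the isoflavones. With flavopiridol at 3, which blocks transcription kinases, FOS (5.12 ± 0.81) and EGR1 (2.86 ± 0.33) were higher and PHOX2A (−4.64 ± 0.46) and CCNB1 (−2.28 ± 0.25) lower. CPM are shares of the counts, so these values do not show whether the amount of FOS or EGR1 RNA rose. The flavopiridol wells held the lowest total of this experiment (706208) and the lowest correlation of log CPM within a group (0.7904). JQ1 at 10, which displaces BET proteins, lowered the adrenergic genes DDC (−2.86 ± 0.20) and LMO1 (−2.71 ± 0.31). NVP-BEZ-235 at 0.6, a PI3K and mTOR inhibitor, lowered ACAT2 (−2.21 ± 0.26), IDI1 (−2.22 ± 0.34) and PCNA (−2.23 ± 0.22) and raised PPP1R15A (2.30 ± 0.24; SE, n = 3 against 9). Palbociclib at 10, which blocks CDK4 and CDK6, lowered 17 of 21 S phase and 19 of 24 G2 and mitosis genes. Flavopiridol changed 3301 genes, JQ1 2694, NVP-BEZ-235 2190 and palbociclib 1244. Without replicates 1, 2 and 3 in turn the counts were 2199, 2508 and 2483, 1703, 1434 and 1912, 1340, 1377 and 1562 and 692, 753 and 671. At least 50 genes changed with 28 of the 29 treatments, all but 43-19 at 20 (35 genes, 15 without replicate 2). The 4-methyl ether of osajin had exactly 50, and 14 of 21 random splits, the real one included, gave as many. With treatment labels shuffled over the plate, a median of 6 and at most 11 treatments reached 50. Passing this cutoff alone therefore does not show a response. By the older method 25 treatments reached 50, and 43-13 (47 genes), H-osajin (49) and the 4-methyl ether (26) did not, nor did 43-19.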

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

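In this part the regrouping of the time labels was chosen after a first version of that test had been seen, and the other tests were chosen before their results.

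With isopomiferin and pomiferin many genes responded differently at 6 h and at 3 h, and with the null analog few did; a test of that difference raised these results. The effect differed between the times for 844 genes with isopomiferin, 1787 with pomiferin and 5 with the null analog, among them SREBF2, FDFT1, HMGCS1 and DHCR7 of sterol synthesis. The time labels were also exchanged at random within the treated and within the DMSO libraries. With isopomiferin and pomiferin 3 of 41 splits each gave as many genes, the real one included, and with the null analog 4. The highest other counts were 1453, 2104 and 288. In each of the other splits with as many genes the 3 treated libraries of one time and the 3 of the other were exchanged whole, so that they carry the real difference between the times, and the test cannot tell whether chance explains the counts. Splits that mixed the treated libraries gave at most 1, 4 and 3 genes. This reading of the test was made after the counts of the splits had been seen.

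The genes changed by the null analog at 6 h rest on 3 DMSO libraries of that time. Of the 148 genes 85.8% moved the same way at 3 h, where the DMSO libraries are others, and random lists of equal size gave 45.3% to 61.5%, which excludes chance values of the DMSO libraries at 6 h as the whole source. Under pomiferin in the third experiment, with its own controls, 76.2% of the 143 genes measured there moved the same way, against 47.6% to 64.3% for random lists. A candidate explanation is that the null analog shares part of the pomiferin response, cholesterol genes among it. Whether it does so through the same target was not tested.

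Between DMSO at 6 h and mock-treated cells 1206 genes differed, though both groups lack an isoflavone. A difference in depth is excluded, since the mean totals had a ratio of 0.996. Time in culture may account for part: of the 1206 genes 72.2% moved the same way between the null analog at 6 h and at 3 h, libraries that all hold vehicle, against 54% to 59.5% for random lists. That comparison also holds any change with time in the effect of the null analog, which differed in 5 genes, so it does not isolate time. DMSO itself stays open and was not tested apart from time, because the mock-treated libraries carry conflicting time labels. Between DMSO at 6 h and at 3 h only 11 genes differed, and between the null analog at 6 h and at 3 h 137. The step from 3 h to 6 h in DMSO thus gave few calls beside the 1206.

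Spike-in sequences, which no comparison uses, were above 0.01% of the counts in 97 of the 192 libraries of the first experiment (0.0279% to 0.477%) and at most 0.00749% in the others. Whether spiked wells were a separate library batch was judged by gene expression, with at least 50 genes set beforehand as its sign. Between 4 spiked and 8 unspiked control wells 0 genes differed by edgeR, and no other tool was run. At an unadjusted p under 0.05 there were 351 of 9199 genes. In simulated data of this experiment, with 2 wells against 8, only 11.3% of 4-fold changes were found. That share may be too low, because the simulated spread included differences between plates, which the block removes. The share that 4 wells against 8 would find was not simulated. The count of 0 genes therefore cannot tell whether spiked wells were a separate batch. The 46 compounds with both wells spiked had a median of 56 genes changed and the 43 with neither 23 (permutation p = 0.535). This leaves open whether compounds in spiked wells changed more genes, since a p above the threshold does not show that the medians were equal. No biological explanation was tested.

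A DMSO well of the third experiment, replicate 2 of the first set, had CSNK2B at 374.9 CPM against at most 288.9 in the other 8, a sample far from the rest. A well without DMSO in the first experiment, the second one of replicate 2, had TEAD4 at 17.99 CPM against at most 8.098 in the other 3. Of 32 combinations of group and measure tested in this way these 2 stood apart, and chance gives about 1 in 20.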

How the results depend on the processing

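In this part only the older quasi-likelihood method was chosen after the data had been seen; a DESeq2 Wald test of the first experiment was planned and not run. With DESeq2 size factors 52 of 52 counts stayed within 1.5 times their value, with the replicate number as a block 56 of 57, with the Wald test 42 of 49, with the older method 42 of 49, with low counts kept 44 of 52, with pooled controls in the first experiment 2 of 2 and in a fit of only the groups compared 10 of 25. When replicates 1, 2 and 3 were left out in turn 24 of 52, 13 of 52 and 20 of 49 did, where fewer libraries carry the test. In a fit of only the groups compared, where fewer libraries estimate the spread, these TruSeq counts were smaller: isopomiferin at 10 and 3 µM, pomiferin at 10 and 3 µM and the null analog at 3 h (204, 98, 179, 20 and 10), the null analog at 6 h (93), isopomiferin and pomiferin against the null analog and each other at 3 h (463, 253 and 181), the doses of isopomiferin and pomiferin at 3 h (19 and 41), those of isopomiferin at 6 h (310), the time effect of the null analog (3) and DMSO at 3 h and 6 h against mock (4 and 229). The cause of the following shifts was not tested. The Wald test gave more genes for isopomiferin at 3 µM and 3 h (417), pomiferin at 3 µM and 3 h (106), the null analog at 3 h (26), the doses of isopomiferin at 3 h (70), the time effect of the null analog (15), DMSO at 3 h against mock (207) and isopomiferin against pomiferin at 1 (297). The older method gave fewer for the doses of isopomiferin at 3 h (23), 43-13 (47), 43-19 (23), the 4-methyl ether (26), H-osajin (49), isopomiferin against pomiferin at 1 (112) and 43-13 against 43-19 (19). With low counts kept 43-13 gave 273, 43-19 235, the 4-methyl ether 225, H-osajin 289, pomiferin against H-pomiferin 657, 43-13 against 43-19 175, wells without DMSO 124 and compounds of the first experiment with at least 50 genes 90. H-osajin gave 57 with the replicate number as a block, and isopomiferin in the first experiment 877 without the plate as one. With an estimated correlation between genes the number of lists stayed within 1.5 times in 6 of 8 comparisons, while 8 of 13 lists held for pomiferin at 3 h and 2 of 8 for the null analog at 6 h. Leaving out each replicate in turn gave these ranges (lowest to highest, then the full count). TruSeq at 3 h: isopomiferin at 10 µM (193 to 570, full 643) and at 3 µM (70 to 135, full 264), pomiferin (200 to 382, full 642) and (14 to 31, full 52), the null analog (10 to 16, full 16), isopomiferin against the null analog (225 to 547, full 738), pomiferin against it (165 to 355, full 503), the isoflavones (87 to 233, full 372), the doses of isopomiferin (1 to 22, full 44) and of pomiferin (31 to 132, full 165), and DMSO against mock (8 to 396, full 72). TruSeq at 6 h: isopomiferin at 10 µM (2472 to 2964, full 3892) and at 3 µM (1404 to 1938, full 2748), pomiferin (3128 to 3872, full 4825) and (345 to 508, full 850), the null analog (40 to 66, full 148), isopomiferin against the null analog (2411 to 2943, full 3901), the isoflavones (711 to 1482, full 1952), the doses of isopomiferin (196 to 375, full 776) and of pomiferin (1428 to 1938, full 2695), and DMSO against mock (154 to 845, full 1206). Time effects: isopomiferin (279 to 564, full 844), pomiferin (760 to 1177, full 1787) and the null analog (2 to 5, full 5). In the third experiment against DMSO: 43-13 (49 to 63, full 87), 43-19 (15 to 42, full 35), isoosajin (416 to 452, full 752), the 4-methyl ether (29 to 49, full 50), the triacetate (2124 to 2497, full 3255), CX-4945 (1624 to 1964, full 2654), isopomiferin at 15 (1882 to 2569, full 3113), H-osajin (43 to 80, full 99) and H-pomiferin (1296 to 1519, full 2163). Pairs there: pomiferin against osajin (416 to 588, full 1055), its triacetate (108 to 243, full 391) and H-pomiferin (385 to 537, full 1002), osajin against H-osajin (1540 to 1868, full 2665), isoosajin against the ether (182 to 251, full 472), isopomiferin against pomiferin at 1 (25 to 84, full 184), 43-13 against 43-19 (9 to 26, full 33) and CX-4945 against pomiferin (2193 to 2667, full 3559). Second experiment: isopomiferin at 10 for 6 h (69 to 80, full 149) and for 24 h (1269 to 1417, full 2112). First experiment, where a lone well is taken to vary like the other groups: isopomiferin (416 to 958, full 1709) and wells without DMSO (1 to 5, full 7). Named genes, counted once per comparison, kept direction and call in 671 of 674 cases with size factors, 665 of 674 with low counts kept, 584 of 587 with the Wald test, 584 of 588 with the replicate block, 586 of 588 with the older method, 283 of 298 in a fit of only the groups compared, 75 of 86 without the plate block, 85 of 86 with pooled controls, and 621 of 674, 617 of 673 and 556 of 588 without replicates 1, 2 and 3. The others mostly lost their call without a change of direction. These changed direction, and the cause was not tested. Leaving out each replicate in turn put the called genes CTSL with isopomiferin in the first experiment at −0.775 to 2.454 and SLC39A10 in the third experiment at −0.559 to 1.574, the lowest in both without replicate 1. Genes not called with isopomiferin ran, in the first experiment, over −0.228 to 0.567 for CSNK2A1 (negative without replicate 1), −1.51 to 0.413 for MYCN and −7.431 to 0.615 for TEAD4 (both positive without replicate 2; the first value for TEAD4 comes from a well with no count and is no measure of size), and in the second at 24 h over −0.179 to 0.135 for CSNK2B and −0.001 to 0.877 for CSNK2A2 (their signs turned without replicate 2). CSNK2B was there at 0.021 with size factors and 0.019 by the Wald test. In the third experiment CSNK2B ran over −0.251 to 0.043 (positive without replicates 1 and 2: 0.003 and 0.043), and with TruSeq at 6 h CSNK2A1 over −0.041 to 0.041 (positive without replicate 1), with 0.002 in a fit of only the groups compared. HSPA5 with CX-4945 was at 0.011 with size factors and 0.011 by the Wald test. HSPA1A with osajin ran over −0.142 to 0.745 (negative without replicate 3), and against H-osajin over −0.854 to 0.325, with 0.009 and 0.325 without replicates 1 and 2. SLC7A11 between the isoflavones at 6 h ran over −0.284 to 0.004 (positive without replicate 1). With the null analog at 6 h the ranges were −0.135 to 0.026 for TEAD4 (positive without replicate 1), −2.074 to 1.255 for ALDH3A1 (positive without replicate 2), −0.028 to 0.038 for CSNK2B (negative without replicates 2 and 3, −0.003 in the latter), −0.014 to 0.074 for CSNK2A1 and −0.002 to 0.027 for CSNK2A2 (both negative without replicate 3). The correlations of isopomiferin between experiments given in the report, 0.19 to 0.571 over all genes, were 0.441 to 0.862 among genes with at least 30 CPM in both, and 0.134 to 0.489 over all genes with a replicate left out. The plates show mainly large changes. Of 2-fold changes added to simulated data 78% were found in the TruSeq experiment, 10% in the third experiment and 7.18% in the second. Of 4-fold changes 11.3% were found in the first. That last value may be too low, because its simulated spread included differences between plates. The experiments differ in depth, in group sizes and in the spread between libraries, and the parts of these were not told apart.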

Other observations

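The splits for palbociclib and for the times within DMSO and within the null analog were chosen after the counts had been seen, and the other tests in this part before. Libraries of compared groups were split anew into groups of the same sizes, and brackets give the real number of genes and then the highest of the other splits.

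In the TruSeq experiment the 6 libraries of a comparison form 10 splits, too few for a share under 0.05. At 3 h the counts were (643 and 44) for isopomiferin at 10 µM, (264 and 1) at 3 µM, (642 and 1) for pomiferin at 10 µM, (52 and 2) at 3 µM and (16 and 1) for the null analog. At 6 h they were (3892 and 0), (2748 and 1), (4825 and 1), (850 and 0) and (148 and 1) in the same order. Isopomiferin against the null analog gave (738 and 1) at 3 h and (3901 and 1) at 6 h, pomiferin against it (503 and 1) and (4589 and 1), and the isoflavones against each other (372 and 22) and (1952 and 3). The doses of isopomiferin gave (44 and 1) and (776 and 1) and those of pomiferin (165 and 1) and (2695 and 1). Between the times the null analog gave (137 and 1) and DMSO (11 and 3). Against mock-treated cells DMSO gave (1206 and 19) at 6 h and (72 and 466) at 3 h, where 4 of the 10 splits, the real one included, gave as many genes. A split of those 6 libraries with several times the real count points to a structure among them other than DMSO.

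In the second experiment 21 splits were counted for each comparison with the controls named in this paragraph and for no other one. No other split gave as many genes, so the real one was 1 of 21 each time. Apart from those of isopomiferin, these comparisons were taken because they had the most genes changed. No correction was made for their number, so the splits argue against chance without excluding it. For isopomiferin the counts were (149 and 23) at 10 and (60 and 16) at 3.3 after 6 h, and (2112 and 249) and (357 and 38) after 24 h. At 24 h NSC255109 gave (2118 and 103) at 2.5 and (1825 and 94) at 0.85, podofilox (1451 and 168) at 1 and (1403 and 162) at 0.33, NSC3905 (1444 and 97) at 3 and (557 and 50) at 1, narasin (1247 and 88), NSC305798 (951 and 187) and mycophenolate (450 and 11). With a replicate left out several of these counts were far lower: mycophenolate gave 126 to 178 genes, NSC3905 at 1 gave 215 to 273, NSC255109 at 0.85 gave 1087 to 1106 and podofilox at 0.33 gave 782 to 848. The number of treatments with at least 50 genes also exceeded every other split, at 6 h (9 and 1) and at 24 h (20 and 2).

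In the third experiment against DMSO 21 splits each were counted, and for the following treatments no other split gave as many genes. They were pomiferin at 10, 3.3 and 1 (4915 and 1832), (2938 and 869) and (1135 and 404), isopomiferin at 15, 5 and 1 (3113 and 868), (1064 and 177) and (223 and 75), osajin (4016 and 1259), the triacetate (3255 and 1054), H-pomiferin (2163 and 457), isoosajin (752 and 165) and CX-4945 (2654 and 414). The same held for flavopiridol (3301 and 599), JQ1 (2694 and 559), NVP-BEZ-235 (2190 and 339) and palbociclib (1244 and 192), and for the treatments with at least 50 genes (28 and 11). Flavopiridol, JQ1 and NVP-BEZ-235 were taken because they were among the treatments with the most genes. These splits argue against chance without excluding it. Chance may explain the counts of 43-19 (35 and 68), where 18 of the 21 splits gave as many genes, and of the 4-methyl ether (50 and 74), where 14 did. H-osajin (99 and 65) and 43-13 (87 and 71) also exceeded all their other splits. Their margins were small, which was weighed only after the counts had been seen, so chance stays open for them. The medians of those splits were 47.5 and 38.5 genes, and by the older method neither treatment reached 50. No correction was made for the number of treatments split in this way. The pairs of relatives have 10 splits, too few for a share under 0.05. They gave (1055 and 66) for pomiferin against osajin, (391 and 53) against the triacetate and (1002 and 32) against H-pomiferin, (2665 and 47) for osajin against H-osajin, (472 and 42) for isoosajin against the ether, (184 and 27) for isopomiferin against pomiferin at 1, (3559 and 60) for CX-4945 against pomiferin and (33 and 42) for 43-13 against 43-19, where 2 of the 10 splits gave as many.

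In the first experiment the compounds with at least 50 genes, in a fit without the plate as a block, exceeded the 20 other splits (33 and 6), which argues against chance. Between wells without DMSO and DMSO wells, fitted alone, 1 gene differed, ARFIP1 (1.68, adjusted p = 0.0145), and 20 of 100 splits gave as many (1 and 4), so chance cannot be excluded.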
